A study of Mus musculus with 29 samples.

How the data were processed

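RNA of macrophages grown from the bone marrow of C57BL/6 mice was measured on 29 Affymetrix 3' expression arrays of 22690 probe sets. Per the labels, cells were kept for 7 days with CSF-1 (10 ng/ml) in Teflon bags and then for 24 h with CSF-1 and 10 ng/ml of IL-4, IL-6, IL-10, IL-4 plus IL-6, IL-4 plus IL-10, or no further cytokine. The groups hold 8 (unstimulated), 5 (IL-4), 5 (IL-6), 3 (IL-10), 5 (IL-4 plus IL-6) and 3 (IL-4 plus IL-10) arrays, and no array was left out. The number of arrays limits the precision of every value.

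The deposited values are log2 intensities that the authors made with RMA, per the submitters' processing notes, a method that corrects background, normalizes by quantiles and gives 1 log2 value per probe set. The notes also name GCOS 1.4, without its role. The values run from 2.45 to 15.13, and the highest lies above the natural logarithm of the largest 16-bit intensity (11.09), so the scale, whose base the notes leave out, is log2 and not the natural logarithm. The RMA version, the probe annotation used and whether all 29 arrays were normalized together are not given, and no detection calls are among the values used here. Array medians lie between 6.95 and 7.03, correlations between arrays between 0.973 and 0.998, and no arrays were identical.

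The values were used as deposited, without further normalization. The gene annotation supplied for these probe sets names exactly 1 gene for 20393 probe sets, several genes for 691 (not used) and none for 1606, of which 1555 are not controls. Symbols were looked up by gene identifier in the reference gene table, where 20351 probe sets were found, 29 were not and 0 changed name. Of a gene's probe sets, the one with the highest mean over all arrays stood for the gene. Genes were tested when at least 3 arrays lay above the median of all values (log2 6.99), which left 7153 of 12393.

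All groups were fitted together with limma 3.58.1 in R 4.3.3 (linear model by group, moderated two-sided tests, Benjamini-Hochberg adjustment over the genes tested). A gene was called at an adjusted p under 0.05. The 13 comparisons were each stimulation against unstimulated, each combination against its single cytokines, IL-10 against IL-6, the combinations against each other, and the interactions of IL-4 with IL-6 and of IL-4 with IL-10. An interaction is the combination minus both single cytokines plus unstimulated, on the log2 scale, so 0 means that the effects add.

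The 27 gene lists were alternative activation, STAT3-responsive genes, cathepsins, cystatins and stefins, lysosome, both branches of the unfolded protein response (IRE1-XBP1 with ATF6, and PERK-ATF4), secretory pathway transport, type I interferon response, classical inflammatory activation, MHC class II presentation and cell cycle. Further lists were scavenger, complement and Fc receptors, cholesterol biosynthesis, glycolysis, fatty acid oxidation, matrix proteases and growth factors, cytokine receptors and JAK-STAT, heat shock and hypoxia. Cell type lists held markers of macrophages, neutrophils, lymphocytes and NK cells, mast cells with basophils and eosinophils, dendritic cells, fibroblasts and stroma, and erythroid cells with megakaryocytes. Lists with at least 3 measured genes were tested with limma's camera (two-sided, preset correlation 0.01, adjusted over the lists of a comparison), again with an estimated correlation, and with fry. Camera asks whether a list's genes differ from the other genes tested. A list's score on an array is the median over its genes after subtracting each gene's mean over all unstimulated arrays. The lists, the tests, most alternatives and the rule for naming genes were fixed before the data were examined.

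Genes are named by that rule. In each comparison it takes the 8 largest increases and the 8 largest decreases among called genes whose groups' values do not overlap (for interactions, among called genes). It adds up to 4 called genes with the largest change from each list, or up to 2 as values where none is called. It also takes Socs3, Arg1, Ctsb, Ctsl, Ctss, Ctsz, Ern1, Xbp1 and Hspa5 throughout, as readouts of STAT3, STAT6, the cathepsins and the unfolded protein response. Not every gene that the rule takes from a list is printed. Jchain, Iglv1 and Ighm in the comparison of unstimulated arrays fall outside it and were chosen after their values were seen.

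Alternatives were quantile normalization, median centring, no filter, a filter at the 75th percentile (log2 9.16), the mean of a gene's probe sets, every probe set by itself, eBayes with trend and robust, array weights, and only the groups compared. Others were the replicate number as a block, a term for the 2 sets of arrays, thresholds of 0.01 and of an absolute log2 difference of 1, and leaving out each array in turn. After the data were seen, a term for the set with the number within the set as a random block, and arrays of 1 set only, were added.

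Whether replicate numbers pair the arrays was checked from correlations of deviations from the group means. Between unstimulated replicates 1 to 5, IL-4, IL-6 and IL-4 plus IL-6, same-numbered arrays correlated at 0.415 to 0.700 (all 30 pairs over 0.1), and each of the 20 arrays correlated best with its own number. IL-10 and IL-4 plus IL-10 gave 0.596 to 0.776 (3 of 3 pairs). Unstimulated replicates 6 to 8 correlated with arrays of the IL-10 groups numbered 5 lower at 0.116 to 0.451 (6 of 6 pairs). Between the sets, same-numbered arrays had a median of -0.331 (8 of 24 pairs over 0.1). The numbers thus pair arrays within a set, and the pairing comes from the data, since the labels give only the numbers.

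The steps were tested on simulated data with 200 of the 7153 genes changed. At a log2 change of 0.25, recovery ran from 38.8% (IL-4 and IL-10 interaction) to 76.1% (IL-4 against unstimulated). At a change of 1 it was at least 98.5% in each comparison. False calls ran from 1.63% to 7.01% of those made. Camera found a list of 40 genes shifted by 0.2 in all 13 comparisons and an unshifted one in none (unadjusted p 0.319 to 0.959). Correlated genes were not simulated, so false calls of real lists stay untested.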

Results

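Macrophages grown from mouse bone marrow with CSF-1, the growth factor that drives macrophage differentiation, were kept for 24 h without further cytokine (8 arrays) or with IL-4 (5), IL-6 (5), IL-10 (3), IL-4 plus IL-6 (5) or IL-4 plus IL-10 (3). The question behind the comparisons is how IL-6 and IL-10, which signal through STAT3, act alone and together with IL-4, which signals through STAT6, with the cathepsin proteases and the IRE1 branch of the unfolded protein response as readouts. The first principal component of all probe sets held 47.3% of their variance and parted the groups that received IL-4 from those that did not. Only the unstimulated group has replicates 6 to 8. These were taken as the controls of the IL-10 groups (second set), and replicates 1 to 5 as those of the IL-4, IL-6 and IL-4 plus IL-6 groups (first set). The labels do not state these 2 sets, which are inferred from the replicate numbers. Between unstimulated replicates 6 to 8 and 1 to 5, 1033 genes differed, 641 higher and 392 lower, among them transcripts of the B-cell lineage such as Jchain (log2 -2.15) and Iglv1 (-2.01). The log2 difference between the 3' and 5' control probe sets of Actb, a measure of RNA quality, moved with the set too, at 0.441 ± 0.070 (SD) in replicates 6 to 8 and 0.318 ± 0.0089 (SD) in replicates 1 to 5. The labels do not say whether arrays came from separate mice or cultures, so every p-value measures the spread between these arrays. Log2 differences are given with their standard error (SE), folds are their antilogs, and padj is the adjusted p. For a list, the numbers of genes called higher and lower stand before the padj of its test, and its other measured genes were not called. Where a list lost its call with an estimated correlation between genes, that padj follows as estimated padj. Differences and interactions of at least 1 in absolute log2 are counted as large. Of 1148 results of named genes in pairwise comparisons, 247 have 1 group with a mean under the intensity filter (log2 6.99). Signal over background was not tested there, so their log2 values and ranks may be limited by background. No folds are given for them, nor for interactions. Of 206 interactions of named genes, 61 have at least 1 unstimulated or single-cytokine mean under the filter, and 17 all of these, so their sizes and ranks cannot be read. In 49 of the 1148 pairwise results both means lie under the filter, and such differences are not read as changes in expression. Among them are Gpr34 with IL-4 (3.85 against 6.91) and both combinations, Ryr1 with IL-10 and Adgre4 between IL-4 plus IL-10 and IL-4. They rank among the largest decreases and are left out.

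**Figure D1:**
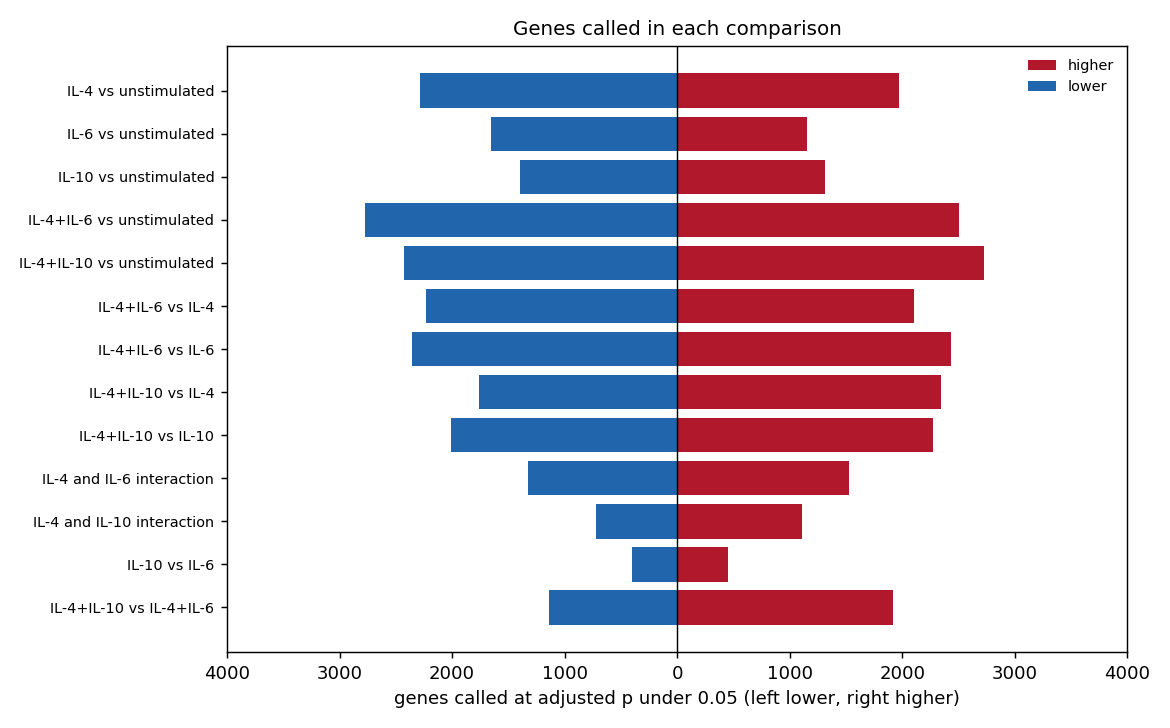
Genes called higher (right, red) and lower (left, blue) in each comparison, of 7153 tested, at an adjusted p under 0.05.

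IL-4 alone (5 arrays against 8) had its largest positive differences in Rnase2a, a ribonuclease of the eosinophil-associated family (log2 9.14 ± 0.14), Retnla, a secreted resistin-like protein (log2 8.55 ± 0.092), and Arg1, the arginase that turns arginine into ornithine and urea (7.75 ± 0.076). The unstimulated means of Rnase2a (3.99), Retnla (6.01) and Arg1 (3.83) lie under the filter, as do those of Arg1 with IL-6 (4.25) and IL-10 (3.73), so their order is not read. The lectin Mgl2, the ribonuclease Ear3, the fusion-associated membrane protein Ocstamp, the feedback inhibitor Socs2 and the retinoic acid enzyme Aldh1a2 followed, from log2 6.38 down to 4.57. Lower with IL-4 were the adhesion receptor Adgre4 (log2 -3.82 ± 0.18) and the iron exporter ferroportin (Slc40a1, log2 -3.00 ± 0.096, 8.02-fold). They were joined by Ctla2b, the pentraxin Nptx1, Ms4a6b, the prostaglandin-degrading enzyme Hpgd and the fractalkine receptor Cx3cr1, the last at -2.705 ± 0.18. Socs3, a feedback inhibitor induced by STAT3, was under the filter in both groups (-0.51 ± 0.11), while the STAT5 and STAT6 targets Cish (2.64 ± 0.14) and Socs1 (1.96 ± 0.092) rose. Members of the alternative activation list rose nearly throughout (30 higher and 0 lower of 31, padj = 4.23e-28). Interferon-response transcripts were lower (3 higher and 22 lower of 29, padj = 5.28e-07, estimated padj = 0.287), with Ifit3 at -2.04 ± 0.115, Oas2 at -1.84 ± 0.086 and Cxcl10 at -1.78 ± 0.12. Scavenger, complement and Fc receptors were lower too (3 higher and 22 lower of 25, padj = 6.7e-07, estimated padj = 0.175), with Stab1 at -2.29 ± 0.089 and the high-affinity IgG receptor Fcgr1 at -2.26 ± 0.063. Chaperones and folding enzymes of the IRE1-XBP1 and ATF6 list rose (29 higher and 6 lower of 42, padj = 3.41e-06, estimated padj = 0.0998), led by the disulfide isomerase Pdia4 (1.07 ± 0.063). The PERK-ATF4 list rose as well (17 higher and 2 lower of 25, padj = 0.000909, estimated padj = 0.355), where the serine-synthesis enzyme Psat1 rose 2.30-fold. All 7 measured genes of MHC class II presentation were called higher (7 higher and 0 lower of 7, padj = 0.00627, estimated padj = 0.444), including its master regulator Ciita (1.25 ± 0.24). When adjusted over the list alone, counts were 3 higher and 23 lower in the type I interferon response list and 29 higher and 7 lower in the IRE1-XBP1 and ATF6 list. In all, 4254 genes were called, 1973 higher and 2281 lower, 293 large (138 higher and 155 lower), and 4179 with a term for the set.

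IL-6 alone (5 arrays against 8) raised the gap-junction protein Gja1 (connexin 43) most (log2 5.35 ± 0.13), then Socs3 (log2 4.95 ± 0.11) and the endothelin receptor Ednrb (log2 3.63 ± 0.17). The chemokines Ccl12 and Ccl8, the acute-phase protein Saa3, the IL-4 receptor chain Il4ra (log2 2.91 ± 0.098, 7.50-fold) and the metalloprotease inhibitor Timp1 rose by log2 2.58 to 3.31. Nptx1 fell most (log2 -4.06 ± 0.22), and Cav1, Cpe, Enc1, Penk, Hpgd, Serpinb6b and Hmga2 were lower, from log2 -1.94 to -1.315. Arg1 differed by 0.42 ± 0.076 between means under the filter, and the mannose receptor Mrc1 rose 3.22-fold. The STAT3-responsive list was higher (24 higher and 2 lower of 28, padj = 2.56e-18), Stat3 itself rising 2.01-fold and the transcription factor Nfil3 rising 3.28-fold. Folding enzymes of the IRE1-XBP1 and ATF6 list rose (32 higher and 0 lower of 42, padj = 1.95e-16), with Pdia4, Sdf2l1 and Manf 1.61 to 1.74-fold higher. Enzymes of cholesterol synthesis rose too (18 higher and 0 lower of 19, padj = 1.46e-13), among them Pmvk (0.83 ± 0.051), Fdps (0.81 ± 0.080) and Mvd (0.70 ± 0.060). Scavenger, complement and Fc receptors were higher (18 higher and 4 lower of 25, padj = 8.12e-07, estimated padj = 0.138), with Fcgr4 up 3.15-fold and Fcgr1 2.71-fold. So were interferon-response genes (20 higher and 1 lower of 29, padj = 1.43e-06, estimated padj = 0.225). Cytokine receptors and JAK-STAT components were higher (14 higher and 3 lower of 31, padj = 4.42e-06, estimated padj = 0.185). Secretory pathway transport rose slightly in median, by 0.088 (23 higher and 2 lower of 48, padj = 3.99e-05, estimated padj = 0.0556). Classical inflammatory genes were higher (9 higher and 1 lower of 17, padj = 0.000427, estimated padj = 0.174), Il1b by 2.52-fold. Cell cycle transcripts were lower (0 higher and 28 lower of 37, padj = 4.4e-06, estimated padj = 0.421), with the mitotic genes Cdc20 at -0.58 ± 0.10 and Nusap1 at -0.565 ± 0.099. Counts adjusted over the list alone came to 18 higher and 5 lower in the scavenger, complement and Fc receptor list, 20 higher and 2 lower in the type I interferon response list and 14 higher and 4 lower in the cytokine receptor and JAK-STAT list. The test called 2808 genes, 1152 higher and 1656 lower, 120 large (92 higher and 28 lower), and 2526 with a term for the set. The arrays with IL-6 had the lowest mean 3' to 5' difference of Actb, at 0.248 ± 0.019 (SD).

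IL-10 alone (3 arrays against 8) shared 7 of its 8 largest increases with the 8 of IL-6. Socs3 (log2 5.64 ± 0.13), Gja1 (log2 5.62 ± 0.155) and Saa3 (log2 4.43 ± 0.27, 21.5-fold) rose most, followed by Ednrb, Ccl12, Il4ra, Ccl8 and the fibrinogen-like protein Fgl2, by log2 2.65 to 3.52. Nptx1 was lower (-2.80 ± 0.27). The receptor kinase Axl, Hpgd, the antioxidant enzyme Gpx3, the urokinase Plau, the vascular growth factor Vegfa and the transcription factor Egr2 were 2.93 to 3.25-fold lower. The STAT3-responsive list was higher (21 higher and 1 lower of 28, padj = 2.11e-13; Nfil3 3.56-fold, Stat3 2.13-fold). Cholesterol synthesis rose with all its measured genes (19 higher and 0 lower of 19, padj = 4.26e-12), Pmvk by 0.97 ± 0.060. The IRE1-XBP1 and ATF6 list was higher (28 higher and 2 lower of 42, padj = 1.85e-10), Manf by 0.77 ± 0.052. Cell cycle genes were lower (0 higher and 26 lower of 37, padj = 2.77e-06, estimated padj = 0.53), but on 2 of 3 arrays. Their scores were 0.064, -0.55 and -0.56 on IL-10 replicates 1, 2 and 3 and -0.18 to 0.18 on the unstimulated arrays, and the list's median went from -0.34 to -0.59 without replicate 1. Higher were cytokine receptors and JAK-STAT components (14 higher and 1 lower of 31, padj = 0.000145, estimated padj = 0.394), secretory transport (20 higher and 2 lower of 48, padj = 0.00217, estimated padj = 0.165) and classical inflammatory genes (9 higher and 1 lower of 17, padj = 0.00217, estimated padj = 0.3). Among the last, Il1b rose 4.73-fold. The interferon-response list was not called (3 higher and 7 lower of 29, padj = 0.253), although Oasl2 (-0.80 ± 0.089) and Oas3 (-0.77 ± 0.080) fell. Arg1, under the filter in both groups, did not pass the test (-0.097 ± 0.090, padj = 0.419). The counts adjusted over the list alone changed to 21 higher and 2 lower in the STAT3-responsive list and 2 higher and 6 lower in the type I interferon response list. The 2704 genes called, 1309 higher and 1395 lower, included 149 large (94 higher and 55 lower). There were 2016 called with a term for the set and 1394 from the second set alone.

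IL-6 and IL-10 were each compared with the same 8 unstimulated arrays, so part of any likeness between their effects comes from the shared controls. Across 7153 genes the log2 effects correlated at r = 0.840 with a covariance of 0.0889. Groups simulated without any effect but with these shared controls gave a mean r of 0.300 (highest 0.561) and a covariance of 0.00227. Genes called higher with both cytokines numbered 810 (210.8 from the product of the counts over the genes tested), those called lower with both 948 (323.0), and 11 were called in opposite directions. The signs were equal for 72.5% of genes, against 60.5% in the simulations. With separate controls, IL-6 against unstimulated replicates 1 to 5 and IL-10 against replicates 6 to 8, r was 0.944 and the covariance 0.0940. There were 607 genes higher in both (108.9), 670 lower in both (151.0), 1 opposite and equal signs for 82.9% of genes.

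IL-4 plus IL-6 (5 arrays against 8 unstimulated) gave the most called genes of the 5 comparisons with unstimulated cells. Arg1 rose most (10.38 ± 0.076), to a mean of 14.21, near the highest value on any array (15.13). Rnase2a, Retnla, the chemokine Ccl8 (log2 8.515 ± 0.15), Gja1, the eosinophil chemoattractant Ccl24, the chitinase-like Chil4 and the lectin Cd209e rose by log2 6.87 to 8.61. Adgre4 (log2 -5.68 ± 0.18), Nptx1, Slc40a1 (log2 -4.445 ± 0.096), the GTPase-activating Arap3, Hpgd, Axl and the Toll-like receptor Tlr2 fell, the last at -3.47 ± 0.14. Alternative activation genes were higher (27 higher and 1 lower of 31, padj = 1.47e-14). The IRE1-XBP1 and ATF6 list rose (36 higher and 2 lower of 42, padj = 2.36e-11), its median log2 of 0.62 standing against 0.22 with IL-4 and 0.24 with IL-6 alone. Pdia4 was 8.63-fold and Pdia6 2.70-fold higher. Secretory pathway transport was higher (37 higher and 4 lower of 48, padj = 3.57e-07), including the cargo receptor Lman1 (0.78 ± 0.042), the SNARE Bet1 (0.74 ± 0.056) and the COPII coat protein Sec23b (0.71 ± 0.032). Cholesterol synthesis was higher throughout (19 higher and 0 lower of 19, padj = 1.69e-07, estimated padj = 0.157), Mvd by 3.55-fold. The PERK-ATF4 list was higher (21 higher and 1 lower of 25, padj = 4.18e-06, estimated padj = 0.219). STAT3-responsive genes were higher in balance (18 higher and 6 lower of 28, padj = 0.00575, estimated padj = 0.414), Socs3 by 4.625 ± 0.11. Cell cycle genes were lower (0 higher and 35 lower of 37, padj = 1.01e-07, estimated padj = 0.481), with thymidine kinase Tk1 at -1.67 ± 0.11 and the kinesin Cenpe at -1.38 ± 0.125. The haemoglobin scavenger receptor Cd163 rose (4.01 ± 0.105), as did Ccl7 (5.61 ± 0.13). Near-identical genes such as Chil3 and Chil4, Rnase2a and Ear3, the Cd209 family and Ccl2 and Ccl12 may share probes, and RMA compresses large folds. The counts adjusted over the list alone were 0 higher and 36 lower in the cell cycle list, with no other change among the lists above. Of the genes tested, 5281 were called, 2505 higher and 2776 lower, 637 large (285 higher and 352 lower), and 5231 with a term for the set.

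IL-4 plus IL-10 (3 arrays against 8 unstimulated) raised Arg1 most (10.02 ± 0.090). Retnla, Rnase2a, Ccl8 (log2 7.82 ± 0.17), Ccl24, the RNA helicase Ddx4, Mgl2 and Gja1 were higher, by log2 5.76 to 8.68. Adgre4 (log2 -5.82 ± 0.22), Slc40a1, Hpgd, Nptx1, thrombospondin (Thbs1), Tlr2 and Arap3 were lower, the last at -3.04 ± 0.11. Alternative activation genes rose nearly throughout (29 higher and 0 lower of 31, padj = 2.11e-17). Every measured gene of cholesterol synthesis rose (19 higher and 0 lower of 19, padj = 2.85e-08, estimated padj = 0.106), Mvd by 3.77-fold and Fdps by 3.00-fold. The IRE1-XBP1 and ATF6 list was higher (33 higher and 4 lower of 42, padj = 9.45e-08), with Pdia4 up 5.00-fold and Creld2 2.48-fold. So was the PERK-ATF4 list (22 higher and 0 lower of 25, padj = 4.74e-06, estimated padj = 0.208). Secretory transport was higher (34 higher and 6 lower of 48, padj = 0.000195, estimated padj = 0.106), the COPI subunit Copg1 by 0.68 ± 0.047. Interferon-response genes were lower (5 higher and 20 lower of 29, padj = 0.000195, estimated padj = 0.425), Ifit3 at -2.56 ± 0.14. Cell cycle genes (1 higher and 27 lower of 37, padj = 0.000222, estimated padj = 0.617) and scavenger, complement and Fc receptors (4 higher and 17 lower of 25, padj = 0.00381, estimated padj = 0.425) were lower as well. Socs3 rose (3.54 ± 0.13), less than with IL-10 alone (5.64 ± 0.13). When adjusted over the list alone, counts were 33 higher and 5 lower in the IRE1-XBP1 and ATF6 list, with no other change. The 5156 genes called divided into 2726 higher and 2430 lower, 540 large (265 higher and 275 lower), and 4753 were called with a term for the set.

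**Figure D2:**
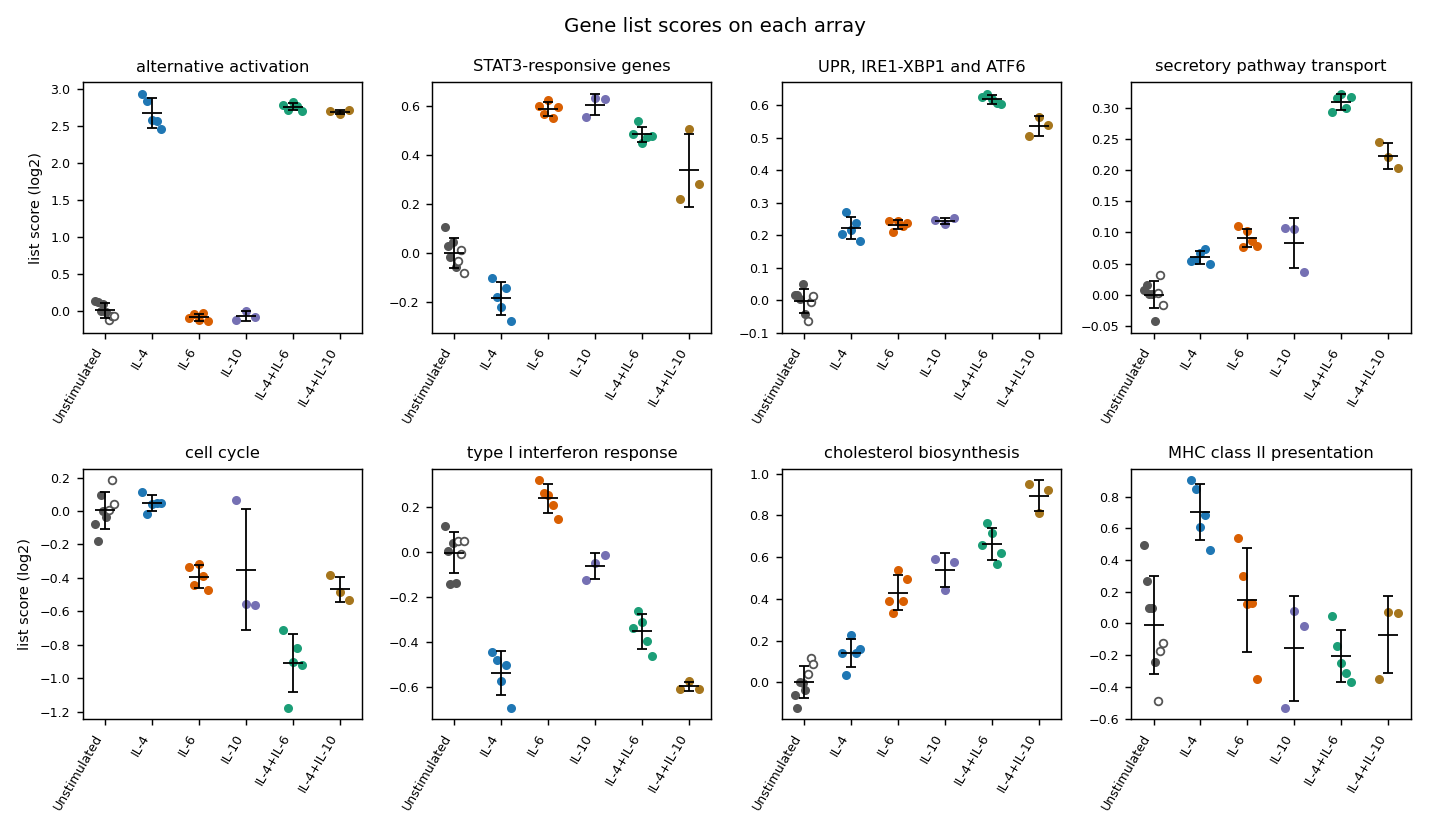
Score of 8 gene lists on each array (log2, median over members after subtracting each gene's mean over the unstimulated arrays), by group. Open circles are unstimulated replicates 6 to 8, dashes are means and bars are SD.

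Adding IL-6 to IL-4 (5 arrays against 5 with IL-4) raised Gja1 (log2 8.07 ± 0.145), Ccl8 (log2 7.745 ± 0.16), Ccl12, Cd209e, Ednrb, Socs3 (log2 5.135 ± 0.12), the growth factor Pdgfc and the cholesterol hydroxylase Ch25h, the last at 4.73 ± 0.12. Arg1 rose a further 6.17-fold (2.63 ± 0.084). Within the alternative activation list Chil4 (4.57 ± 0.11), Cd209a (4.44 ± 0.16) and Ccl24 (3.83 ± 0.15) rose while the chemokine Ccl17 fell (log2 -2.55 ± 0.12), and the list as a whole was not called (17 higher and 12 lower of 31, padj = 0.232). Ramp1 (log2 -3.265 ± 0.16), Axl, the transcription factor Irf4, Sema4d, Ocstamp, Siglecf and Arap3 were also lower, the last at -2.22 ± 0.105. Every measured gene of the cell cycle list was lower (0 higher and 37 lower of 37, padj = 5.68e-13, estimated padj = 0.353), with Tk1 at -1.36 ± 0.12, Cenpe at -1.24 ± 0.14 and Ccnb2 at -1.22 ± 0.12. Genes of the IRE1-XBP1 and ATF6 list were higher (33 higher and 1 lower of 42, padj = 2.37e-10), Pdia4 by 4.11-fold. Secretory transport rose (39 higher and 2 lower of 48, padj = 3.21e-08), the cargo-receptor subunit Mcfd2 by 0.70 ± 0.035 and Sec23b by 0.615 ± 0.035. Cholesterol synthesis rose (19 higher and 0 lower of 19, padj = 2.07e-07, estimated padj = 0.162). STAT3-responsive genes were higher (20 higher and 5 lower of 28, padj = 1.27e-05, estimated padj = 0.145), Il4ra by 13.5-fold and Cebpd by 6.41-fold. The PERK-ATF4 list (18 higher and 3 lower of 25, padj = 0.00149, estimated padj = 0.476) and interferon-response genes (18 higher and 1 lower of 29, padj = 0.0045, estimated padj = 0.679) were higher too. Of the genes of MHC class II presentation, 6 of 7 were lower and 1 higher (padj = 0.0755, padj = 0.0435 with the replicate number as a block, and padj = 0.679 with an estimated correlation), with Ciita at -1.75 ± 0.27 and H2-Ab1 at -0.96 ± 0.17. Cd163 (3.74 ± 0.12), the Axl ligand Gas6 (7.32-fold) and Timp1 (11.7-fold) rose. Counts adjusted over the list alone came to 39 higher and 3 lower in the secretory pathway list, with no other change. The 4330 called genes comprised 2101 higher and 2229 lower, 383 large (186 higher and 197 lower). All arrays belong to the first set.

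Adding IL-4 to IL-6 (5 arrays against 5 with IL-6) raised Arg1 most (9.96 ± 0.084). Rnase2a, Retnla, Ccl24, Chil4, Mgl2, Cd209e and Ddx4 rose by log2 6.335 to 8.68. Adgre4 (log2 -4.52 ± 0.20), Slc40a1, the NF-kappaB regulator Nfkbiz (log2 -3.52 ± 0.077), Tlr2, the lectins Clec4d and Clec4e, Pcp4l1 and Marcksl1 were lower, the last 8.59-fold. Saa3 (-2.91 ± 0.255), the formyl peptide receptor Fpr2 (-2.72 ± 0.115) and Cxcl10 (-3.05 ± 0.13) also fell. Alternative activation genes were higher (30 higher and 0 lower of 31, padj = 8.88e-21). Both unfolded protein response lists rose, IRE1-XBP1 and ATF6 (30 higher and 3 lower of 42, padj = 1.95e-06, estimated padj = 0.0623) as well as PERK-ATF4 (22 higher and 0 lower of 25, padj = 4.46e-06, estimated padj = 0.196). Secretory transport (35 higher and 2 lower of 48, padj = 3.15e-05, estimated padj = 0.0623) and cholesterol synthesis (14 higher and 0 lower of 19, padj = 0.00728, estimated padj = 0.442) were higher. Scavenger, complement and Fc receptors were lower (3 higher and 20 lower of 25, padj = 4.46e-06, estimated padj = 0.196), although Cd163 rose (4.20 ± 0.12). Interferon-response genes (5 higher and 22 lower of 29, padj = 4e-05, estimated padj = 0.442), cell cycle genes (0 higher and 30 lower of 37, padj = 3.15e-05, estimated padj = 0.533) and classical inflammatory genes (4 higher and 10 lower of 17, padj = 0.0273, estimated padj = 0.442) were lower. The counts adjusted over the list alone were 31 higher and 3 lower in the IRE1-XBP1 and ATF6 list and 23 higher and 0 lower in the PERK-ATF4 list, with no other change. Called genes numbered 4785, 2431 higher and 2354 lower, 486 large (216 higher and 270 lower), again within the first set.

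Adding IL-10 to IL-4 (3 arrays against 5 with IL-4) raised most 7 of the 8 genes that IL-6 had raised most, and Ccl24. These were Ccl8 (log2 7.05 ± 0.19), Gja1 (log2 6.12 ± 0.17), Ccl12, Socs3 (log2 4.05 ± 0.14), Cd209e, Pdgfc, Ccl24 and Ch25h, the last at 3.42 ± 0.14. Arg1 rose further (2.26 ± 0.097, size again not readable). Among the genes lower were Axl (log2 -2.35 ± 0.16, 5.11-fold), the peroxisomal transporter Abcd2, Ramp1 and Sema4d. Ms4a1, Jchain and Igkv8-30, transcripts of B-lineage cells, were also lower. Their differences of -2.47, -2.26 and -2.04 became -0.47 (padj = 0.553), -0.11 (padj = 0.906) and 0.058 (padj = 0.954) with a term for the set. Cholesterol synthesis was higher (19 higher and 0 lower of 19, padj = 8.55e-10, estimated padj = 0.0959), Mvd by 2.41-fold and the lanosterol synthase Lss by 2.12-fold. The IRE1-XBP1 and ATF6 list was higher (29 higher and 2 lower of 42, padj = 1.81e-05, estimated padj = 0.0959), Pdia4 by 2.38-fold. Secretory transport (30 higher and 2 lower of 48, padj = 0.000131, estimated padj = 0.0959) and the PERK-ATF4 list (20 higher and 1 lower of 25, padj = 0.000416, estimated padj = 0.498) were higher. STAT3-responsive genes were higher on balance (15 higher and 6 lower of 28, padj = 0.00574, estimated padj = 0.498), Il4ra by 4.80-fold. Cell cycle genes were lower (0 higher and 33 lower of 37, padj = 1.11e-09, estimated padj = 0.581), with Ccne2 at -1.18 ± 0.18 and Cenpe at -1.02 ± 0.16. Alternative activation genes were not called as a list (14 higher and 10 lower of 31, padj = 0.21, median 0.20), but were with a term for the set (median 0.22, padj = 0.00049). When adjusted over the list alone, counts were 21 higher and 1 lower in the PERK-ATF4 list and 0 higher and 34 lower in the cell cycle list, with no other change. These groups belong to different sets. There were 4100 genes called, 2340 higher and 1760 lower, 217 large (129 higher and 88 lower). With a term for the set 2370 were called, 1215 higher and 1155 lower.

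Adding IL-4 to IL-10 (3 arrays against 3 with IL-10) raised Arg1 most (10.11 ± 0.11). Rnase2a, Retnla, Ccl24, Ddx4, Mgl2, Chil4 and the PD-1 ligand Pdcd1lg2 were higher, by log2 5.54 to 8.69. Adgre4, Slc40a1, Nfkbiz (log2 -3.71 ± 0.10), Saa3, the lectins Clec4n and Clec4e, Ms4a6b and Tlr2 fell, from log2 -4.67 to -3.30. Socs3 fell (log2 -2.105 ± 0.15, 4.30-fold), and STAT3-responsive genes as a list were lower (4 higher and 20 lower of 28, padj = 0.000412, estimated padj = 0.223). Alternative activation genes were higher (30 higher and 0 lower of 31, padj = 2.46e-25), as was the PERK-ATF4 list (19 higher and 0 lower of 25, padj = 0.000138, estimated padj = 0.223). The IRE1-XBP1 and ATF6 list was higher (25 higher and 4 lower of 42, padj = 0.000423, estimated padj = 0.223), the membrane protein Wfs1 by 3.13-fold. Cholesterol synthesis (12 higher and 0 lower of 19, padj = 0.00188, estimated padj = 0.334) and secretory transport (24 higher and 4 lower of 48, padj = 0.0119, estimated padj = 0.223) were higher too. Scavenger, complement and Fc receptors were lower (3 higher and 20 lower of 25, padj = 7.69e-06, estimated padj = 0.223). Interferon-response genes (4 higher and 18 lower of 29, padj = 0.000412, estimated padj = 0.348; Cxcl10 -2.68 ± 0.17) and classical inflammatory genes (5 higher and 10 lower of 17, padj = 0.0219, estimated padj = 0.334) were also lower. Counts adjusted over the list alone came to 26 higher and 4 lower in the IRE1-XBP1 and ATF6 list and 4 higher and 19 lower in the type I interferon response list, with no other change. With 4284 genes called, 2277 were higher and 2007 lower, 469 large (219 higher and 250 lower), all arrays belonging to the second set.

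The interaction of IL-4 and IL-6, the change that IL-6 brought on top of IL-4 minus its change in unstimulated cells on the log2 scale, was positive for Cd209e (6.00 ± 0.14), Ccl8 (4.78 ± 0.22), Chil4, Cd209a, Ccl24, Cd163 (3.93 ± 0.16), the retinol carrier Rbp4 and Ch25h. Under the filter were the unstimulated and both single-cytokine means of Cd209e, Chil4, Cd209a, Cd163, Rbp4 and Ch25h, the unstimulated and IL-4 means of Ccl8 and the unstimulated and IL-6 means of Ccl24, so these values show a rise with both cytokines and not its excess over a sum. Negative interactions were found for Slamf9 (log2 -3.16 ± 0.14), Ccl17, the chemokine receptor Ccr2 (log2 -2.46 ± 0.14), Ciita (log2 -2.33 ± 0.36), Clec4b1, the clotting factor F13a1, Tmem176b and Ramp1. Arg1 gave 2.20 ± 0.11, with its unstimulated and IL-6 means under the filter (as had Ccl17), while Socs3, whose unstimulated and IL-4 means were under it, did not pass (0.19 ± 0.16, padj = 0.371). Cell cycle genes had negative interactions (0 higher and 34 lower of 37, padj = 5.58e-10, estimated padj = 0.478), Tk1 at -0.85 ± 0.16. So had MHC class II genes (0 higher and 6 lower of 7, padj = 0.0128, estimated padj = 0.478), H2-Ab1 at -1.13 ± 0.235. Secretory transport had positive ones (25 higher and 2 lower of 48, padj = 0.000109, estimated padj = 0.196), Sec23b at 0.48 ± 0.047 and Mcfd2 at 0.43 ± 0.047. The PERK-ATF4 list was positive too (12 higher and 0 lower of 25, padj = 0.00996, estimated padj = 0.478). Classical inflammatory genes had negative interactions (3 higher and 10 lower of 17, padj = 0.0413, estimated padj = 0.478), Tlr2 at -1.675 ± 0.21 and Il1b at -1.35 ± 0.20, but Ccl7 at 2.07 ± 0.19. The call was lost without unstimulated replicate 2 (padj = 0.0535), unstimulated replicate 4 (padj = 0.0506) or IL-4 plus IL-6 replicate 4 (padj = 0.0553). Alternative activation genes missed the threshold (14 higher and 6 lower of 31, padj = 0.0572). They passed it with the replicate number as a block (median 0.414, padj = 0.00822; padj = 0.478 with an estimated correlation and no block) and, among others, without unstimulated replicate 7 (padj = 0.0366). The counts adjusted over the list alone were 0 higher and 35 lower in the cell cycle list, 1 higher and 6 lower in the MHC class II list, 13 higher and 0 lower in the PERK-ATF4 list and 14 higher and 7 lower in the alternative activation list, with no other change. Interactions were called for 2858 genes, 1530 positive and 1328 negative, 213 large (107 of them negative), and for 2759 with a term for the set.

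The interaction of IL-4 and IL-10 was positive for Ccl8 (4.04 ± 0.26), Cd209e (3.72 ± 0.16), Ccl24, Bex1, Chil4, the adipokine Adipoq, Msx3, Ccl7 and Arg1 (2.36 ± 0.13). Under the filter were the unstimulated and both single-cytokine means of Cd209e, Chil4, Adipoq and Msx3, the unstimulated and IL-10 means of Ccl24, Bex1 and Arg1, the unstimulated and IL-4 means of Ccl8 and the unstimulated mean of Ccl7, with the same limit. The interaction was negative for the receptor Lifr (log2 -2.435 ± 0.21), F13a1, Saa3 (log2 -2.365 ± 0.40), Slamf9, the cytokine Il1b (log2 -2.02 ± 0.23), Ccr2, Fcrls and the leukotriene receptor Cysltr1. Socs3, its unstimulated and IL-4 means under the filter, had a negative interaction (-1.595 ± 0.19), as had Nfil3 (-1.20 ± 0.12) and Il4ra (-0.90 ± 0.17). STAT3-responsive genes did as a list (4 higher and 15 lower of 28, padj = 5.19e-05, estimated padj = 0.261). Alternative activation genes had positive interactions (14 higher and 2 lower of 31, padj = 0.000115, estimated padj = 0.261), Pdcd1lg2 at 2.19 ± 0.20. So had the PERK-ATF4 list (11 higher and 0 lower of 25, padj = 0.00729, estimated padj = 0.608). Classical inflammatory genes had negative interactions (3 higher and 6 lower of 17, padj = 0.0174, estimated padj = 0.544), a call lost without IL-4 plus IL-10 replicate 1 (padj = 0.0631). The cell cycle list passed (0 higher and 3 lower of 37, padj = 0.00387, estimated padj = 0.773) but rested on IL-10 replicate 1, without which its median was -0.011 (padj = 0.505). When adjusted over the list alone, counts were 5 higher and 18 lower in the STAT3-responsive list, 15 higher and 2 lower in the alternative activation list, 3 higher and 8 lower in the classical inflammatory list and 0 higher and 0 lower in the cell cycle list, the other list keeping its counts. Of 1833 interactions called, 1108 were positive and 725 negative, 121 were large (55 positive and 66 negative), and 1701 were called with a term for the set.

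IL-10 was compared directly with IL-6 (3 arrays against 5), groups of different sets. Interferon-response genes were lower with IL-10 (0 higher and 16 lower of 29, padj = 1.79e-19, estimated padj = 0.0582), with Oasl2 at -0.80 ± 0.096, Ifit3 at -0.77 ± 0.15, Mx1 at -0.85 ± 0.12 and Ifit2 at -0.91 ± 0.175. With a term for the set the list's median was -0.41 (padj = 4.51e-40). Oasl2 (-0.70, padj = 0.0287) and Ifit3 (-1.02, padj = 0.0287) passed with it, while Mx1 (-0.75, padj = 0.174) and Ifit2 (-0.93, padj = 0.395) kept about their differences and lost their calls. Matrix proteases and growth factors were lower (0 higher and 11 lower of 24, padj = 1.16e-08; the collagenase Mmp13 -0.92 ± 0.14, and -0.48, padj = 0.999, with a term for the set), and as a list kept a lower median with it (-0.115, padj = 0.000351). Scavenger, complement and Fc receptors (0 higher and 6 lower of 25, padj = 3.77e-05, estimated padj = 0.476) and the lysosome list (1 higher and 7 lower of 43, padj = 0.000707, estimated padj = 0.512) were lower without that term but not with it (medians -0.006, padj = 0.884, and 0.005, padj = 0.975). The largest positive differences were those of Saa3 (1.38 ± 0.29), the inhibitor of differentiation Id3 (1.27 ± 0.26), Nptx1, Arl2bp, Gabarapl1, Kri1, Rab5c and Preb. The largest negative ones were those of the immunoglobulin and B-cell genes Jchain (-2.50 ± 0.58), Igkv8-30, Iglv1, Ms4a1 and Ighm, of Wdfy3, of fibronectin (Fn1, -1.335 ± 0.27) and of Malat1. Nptx1 and Ms4a1 were under the filter in both groups, and all 16 had padj = 0.999 once a term for the set was added. Without IL-10 replicate 2, 10 of these 16 genes lost their call, with padj from 0.0517 (Ighm) to 0.131 (Iglv1), and Nptx1 did without IL-10 replicate 1 (padj = 0.0523). Socs3 was higher with IL-10 (0.695 ± 0.14, with the term 0.27, padj = 0.999). Arg1 was under the filter in both groups (-0.52 ± 0.097, with the term -0.51, padj = 0.399). Counts adjusted over the list alone came to 0 higher and 21 lower in the type I interferon response list, 0 higher and 9 lower in the scavenger, complement and Fc receptor list and 1 higher and 11 lower in the lysosome list. The test called 850 genes, 448 higher and 402 lower, 20 large (8 higher and 12 lower). With a term for the set limma called 7 (0 higher, 7 lower). The count fell to 89 without IL-10 replicate 2, 477 without IL-10 replicate 1, 467 without IL-6 replicate 4 and 471 without IL-6 replicate 1.

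**Figure D3:**
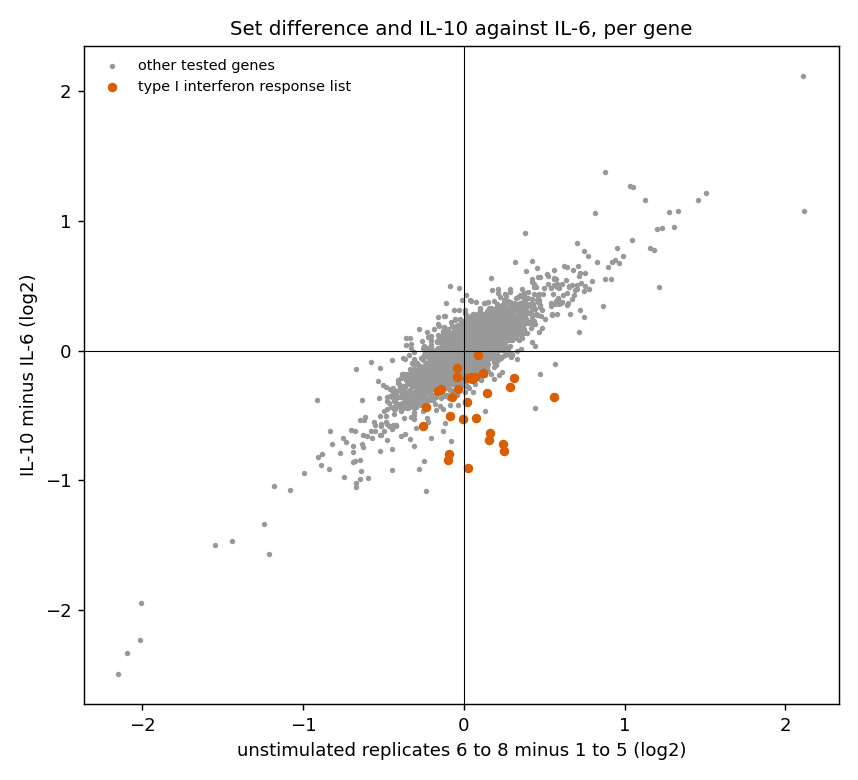
Each gene's difference between unstimulated replicates 6 to 8 and 1 to 5 (horizontal) against its difference between IL-10 and IL-6 (vertical), log2. Interferon-response genes are in orange.

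The combinations were compared with each other (IL-4 plus IL-10, 3 arrays, against IL-4 plus IL-6, 5 arrays), again across the sets. Ccl17 (log2 2.14 ± 0.14), Irf4 (log2 1.37 ± 0.21, 2.58-fold), Ramp1 (log2 1.24 ± 0.18), the fatty acid desaturase Fads2 (1.22 ± 0.17) and Serpinb6b were higher with IL-10. Cd209a (log2 -2.64 ± 0.18, 6.22-fold), Cd209e (log2 -2.57 ± 0.12, 5.93-fold), Ednrb (log2 -2.18 ± 0.22, 4.53-fold) and Gja1 (log2 -1.96 ± 0.17, 3.88-fold) were higher with IL-6. With a term for the set Ccl17 gave 2.16, Irf4 2.19, Cd209a -2.48 and Gja1 -1.98. Cd163 (-1.88 ± 0.13), Chil4 (-1.52 ± 0.13), Il4ra (-1.50 ± 0.13) and Socs3 (-1.09 ± 0.14) were lower with IL-10. Arg1 was lower as well (-0.36 ± 0.097, with the term -0.36, padj = 0.0842), its means of 13.85 and 14.21 too near the top of the scale for the size to be read. The IRE1-XBP1 and ATF6 list was lower with IL-10 (5 higher and 20 lower of 42, padj = 2.12e-05, estimated padj = 0.267), Pdia4 at -0.79 ± 0.081. So were interferon-response genes (0 higher and 12 lower of 29, padj = 2.12e-05, estimated padj = 0.516), Oas2 at -0.545 ± 0.11. STAT3-responsive genes (5 higher and 13 lower of 28, padj = 0.000675, estimated padj = 0.377) and secretory transport (8 higher and 17 lower of 48, padj = 0.00456, estimated padj = 0.377) were lower. Cell cycle genes were higher (21 higher and 0 lower of 37, padj = 9.13e-05, estimated padj = 0.777), Ccnd1 at 0.95 ± 0.15. With that term these 5 lists held 1 higher and 11 lower, 0 higher and 8 lower, 1 higher and 8 lower, 1 higher and 9 lower and 3 higher and 0 lower in the same order, padj from 1.79e-05 to 0.00859. Gabarapl1 (1.47 ± 0.31), Kri1 and the B-lineage transcripts Jchain (-2.46 ± 0.58), Igkv8-30, Iglv1 and Ms4a1 (the last under the filter in both groups) were among the largest differences without that term and had padj from 0.776 to 0.995 with it. Prmt1 (1.63 ± 0.61, padj = 0.032, and -0.49, padj = 0.673, with the term) lost its call without any of 5 arrays. Its padj was 0.0793 without IL-4 plus IL-6 replicate 1, 0.0602 without replicate 5 of that group, and 0.0659, 0.0823 and 0.0753 without IL-4 plus IL-10 replicates 1, 2 and 3. The counts adjusted over the list alone were 5 higher and 21 lower in the IRE1-XBP1 and ATF6 list, 5 higher and 14 lower in the STAT3-responsive list, 8 higher and 18 lower in the secretory pathway list and 24 higher and 0 lower in the cell cycle list. In this comparison 3063 genes were called, 1921 higher and 1142 lower, 59 large (18 higher and 41 lower), and 1159 with a term for the set, 588 higher and 571 lower.

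Among the cathepsins, lysosomal proteases that macrophages also secrete, the transcript of cathepsin L (Ctsl) fell with IL-4 (-0.18 ± 0.028), and rose with IL-6 (0.29 ± 0.028) and IL-10 (0.20 ± 0.033). It rose with IL-4 plus IL-6 (0.42 ± 0.028, 1.34-fold) and IL-4 plus IL-10 (0.32 ± 0.033), with positive interactions of 0.31 ± 0.042 (padj = 1.02e-06) and 0.29 ± 0.049 (padj = 5.72e-05). Cathepsin Z (Ctsz) rose with IL-4 (0.22 ± 0.029) and both combinations (0.20 ± 0.029 and 0.28 ± 0.034). It fell with IL-6 (-0.091 ± 0.029, padj = 0.0132) and IL-10 (-0.12 ± 0.034, padj = 0.00513, 0.0703 without IL-10 replicate 1, and -0.12, padj = 0.226, with arrays of the second set alone). Its interaction was called with IL-10 (0.18 ± 0.050) and not with IL-6 (padj = 0.186). Cathepsin B (Ctsb) rose with IL-6 (0.14 ± 0.026) and IL-4 plus IL-6 (0.175 ± 0.026), and when IL-6 was added to IL-4 (0.20 ± 0.028). With IL-4 plus IL-10 it was 0.033 ± 0.030 against unstimulated (padj = 0.329) and 0.060 ± 0.033 against IL-4 (padj = 0.118), and was called higher with a term for the set (0.091, padj = 0.0107, and 0.15, padj = 0.0032). With IL-4 its value was -0.027 ± 0.026 (padj = 0.38, but -0.061, padj = 0.023 with the replicate block). With IL-10 it was 0.077 ± 0.030 (padj = 0.048), against 0.13 with the set term (padj = 0.00122) and with arrays of the second set alone (padj = 0.105). That call was lost without any of IL-10 replicates 1 to 3 or unstimulated replicates 5 to 8, padj from 0.0561 to 0.137, and without the filter, with array weights or with only the groups compared, padj from 0.123 to 0.221. Its interaction with IL-6 was 0.059 ± 0.038 (padj = 0.231, padj = 0.0217 with the block, but -0.23, padj = 0.0213, with every probe set by itself). Where IL-4 was added to IL-6, Ctsb's probe sets were called in opposite directions, and its value was 0.032 ± 0.028 (padj = 0.32). Between the combinations Ctsb (-0.14 ± 0.033, padj = 0.00113) and Ctsl (-0.11 ± 0.036, padj = 0.0179, 0.151 without IL-4 plus IL-10 replicate 2) did not pass with a term for the set (Ctsb -0.051, padj = 0.421, and Ctsl -0.090, padj = 0.247, its difference nearly kept). For Ctsl in IL-4 plus IL-10 against IL-10 (0.12 ± 0.040, padj = 0.0145) padj was 0.0833 without IL-4 plus IL-10 replicate 3 and 0.0951 with arrays of the second set alone. Cathepsin S (Ctss) was not called in any comparison by limma, with padj from 0.214 to 0.989 over the 13 comparisons and values from -0.059 to 0.031. The values of Ctss (14.46 to 14.64 on the arrays), Ctsb (14.42 to 14.73) and Ctsl (14.07 to 14.81) lie near the top of the scale (15.13), where differences may be compressed, so neither stability nor the sizes of their differences and interactions can be read closely. Cathepsin C (Ctsc) rose with IL-6 (2.34-fold) and IL-10 (2.31-fold) and fell with IL-4 (1.56-fold). Legumain (Lgmn) rose when IL-6 was added to IL-4 (2.56-fold). As a list the 12 measured cathepsins were called only with IL-6 (5 higher and 3 lower of 12, padj = 0.0252, estimated padj = 0.185, and padj = 0.112 with the replicate block), padj ranging from 0.158 to 0.959 in the other comparisons. Secreted protein was not measured.

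**Figure D4:**
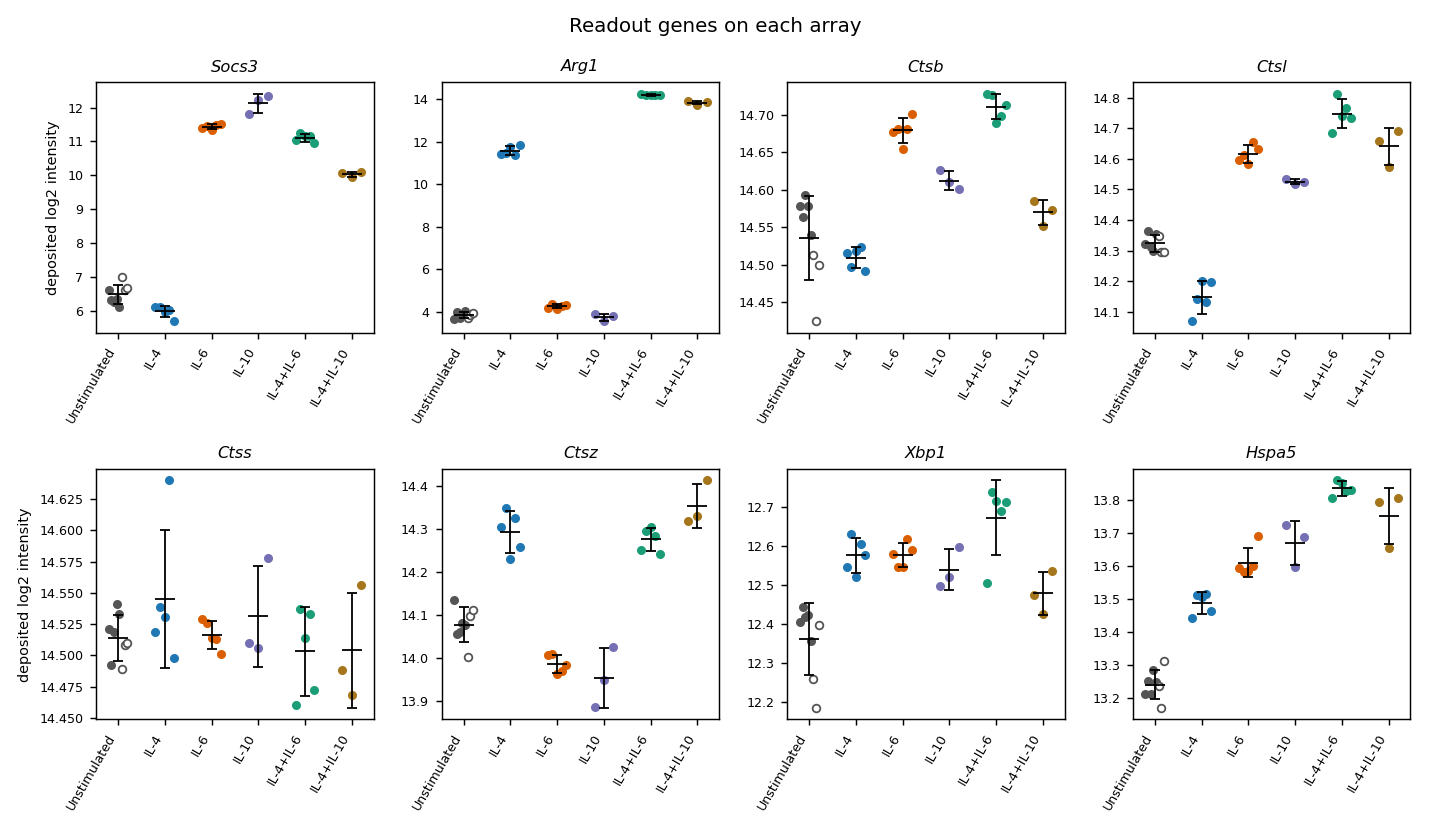
Deposited log2 intensity of 8 readout genes on each array, by group. Open circles are unstimulated replicates 6 to 8, dashes are means and bars are SD.

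Of the unfolded protein response readouts, the sensor IRE1 (Ern1) lay below the intensity filter and was not tested. The arrays measure Xbp1 as total transcript, without telling its spliced form apart. Xbp1 rose with IL-4 (0.215 ± 0.042), IL-6 (0.215 ± 0.042), IL-10 (0.18 ± 0.050, padj = 0.0061, and 0.0541 without IL-10 replicate 3) and IL-4 plus IL-6 (0.31 ± 0.042). With IL-4 plus IL-10 it rose by 0.12 ± 0.050 (padj = 0.038), and by 0.20, still called, with arrays of the second set alone. The call was lost with quantile normalization, without the filter and with only the groups compared. It was also lost without unstimulated replicate 6 (padj = 0.0665) or 7 (padj = 0.0664), or IL-4 plus IL-10 replicate 1 (padj = 0.0787) or 3 (padj = 0.181). The interaction of Xbp1 was negative with IL-10 (-0.275 ± 0.074, padj = 0.00686) and not called with IL-6 (-0.12 ± 0.063, padj = 0.141). IL-4 plus IL-6 against IL-4 and against IL-6 gave 0.097 for Xbp1 (padj = 0.0766 and 0.0698), which passed with the replicate block (padj = 0.0278 and 0.0252) and without IL-4 plus IL-6 replicate 1 (padj = 0.00852 and 0.00733). The chaperone BiP (Hspa5) rose with IL-4 (0.25 ± 0.031), IL-6 (0.37 ± 0.031), IL-10 (0.43 ± 0.037), IL-4 plus IL-6 (0.60 ± 0.031) and IL-4 plus IL-10 (0.51 ± 0.037). It rose when IL-6 (0.35 ± 0.034) or IL-10 (0.26 ± 0.040) was added to IL-4 and when IL-4 was added to IL-6 (0.225 ± 0.034). Adding IL-4 to IL-10 gave 0.083 ± 0.044 (padj = 0.109, and 0.0162 without IL-4 plus IL-10 replicate 2). Its interaction was not called with IL-6 (-0.023 ± 0.046, padj = 0.727). With IL-10 (-0.165 ± 0.054, padj = 0.0254) it was lost without IL-10 replicate 1 (padj = 0.0825), IL-10 replicate 3 (padj = 0.0646) or IL-4 plus IL-10 replicate 2 (padj = 0.128). The interaction of the IRE1-XBP1 and ATF6 list with IL-6 missed the threshold (17 higher and 5 lower of 42, padj = 0.0572). It passed with the replicate block (median 0.108, padj = 0.0129; padj = 0.478 with an estimated correlation and no block) and, among others, without IL-4 plus IL-6 replicate 1 (padj = 0.0474). With IL-10 it had a median of 0.001 and a mean of 0.030, while the test pointed lower (padj = 0.79, 11 higher and 7 lower of 42). Direct comparison of IL-10 with IL-6 gave -0.037 ± 0.054 for Xbp1 (padj = 0.679) and 0.059 ± 0.040 for Hspa5 (padj = 0.338). Comparing the combinations gave -0.19 ± 0.054 for Xbp1 (padj = 0.0051, 0.583 with a term for the set) and -0.084 ± 0.040 for Hspa5 (padj = 0.091).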

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

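The permutation of the cell cycle score within pairs, the RNA quality test of that list, and the requirement that the RNA quality term move other genes, were chosen only after the results were seen.

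Of 148 groups tested for a distant array, 5 had one, against 7.4 by chance at 1 in 20. Groups with IL-10 (3 arrays) were not tested. IL-4 replicate 4 lay apart for Ctss (14.64, nearest 14.54) and the cathepsin score (-0.17, nearest -0.11). IL-4 plus IL-6 replicate 1 had the lowest Xbp1 (12.505, nearest 12.69), and replicate 2 the lowest heat shock score (0.14, nearest 0.30). IL-6 replicate 5 had the highest Hspa5 (13.69, nearest 13.60). No explanation of these was tested.

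The effect of IL-6 differed between cells with and without IL-4, by the test of the interaction, for 2858 genes. Among the readouts these held Arg1 (2.20) and Ctsl (0.31), Arg1 with its unstimulated, IL-6 and IL-10 means under the intensity filter. The lists, given as medians, were PERK-ATF4 (0.255), secretory pathway transport (0.16), classical inflammatory activation (-0.435), MHC class II presentation (-0.99) and cell cycle (-0.60). Each of these 5 calls was lost with an estimated correlation (padj from 0.196 to 0.478). The effect of IL-10 likewise differed for 1833 genes. Its readouts were Arg1 (2.36), Socs3 (-1.595), Ctsl (0.29), Ctsz (0.18), Xbp1 (-0.275) and Hspa5 (-0.165), Socs3 with its unstimulated and IL-4 means under that filter. Its lists were alternative activation (0.30), STAT3-responsive genes (-0.32), PERK-ATF4 (0.25), classical inflammatory activation (-0.36), cell cycle (-0.21) and hypoxia (-0.18). Each of these 6 calls was lost with an estimated correlation (padj from 0.261 to 0.773). The cell cycle median was -0.011 without IL-10 replicate 1, and hypoxia was lost with the set term (padj = 0.0698).

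The secretory pathway list lay above the sum of the IL-4 and IL-6 effects, with a median interaction of 0.156 over 48 genes, a call lost with an estimated correlation (padj = 0.196). Against a shift shared by genes of like intensity, that median stood at percentile 99.99 of 10000 random lists matched on mean intensity, whose medians ran from -0.138 to 0.159. With the Actb 3' minus 5' difference as a covariate, which 570 genes followed, 97.2% of it was kept (0.151), and camera's unadjusted test passed. Its slope rests on spread within groups, so RNA quality differing between groups stays open, as do cell density and other unlabelled culture properties. A hypothesis for other data is that IL-4 and IL-6 together may raise the transport machinery beyond their sum.

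The cell cycle list was lower with IL-4 plus IL-6 than with IL-4 (median -0.98 over 37 genes), a call lost with the estimated correlation of 0.656 (padj = 0.353). Its score was 0.048 ± 0.047 (SD, n = 5) with IL-4 and -0.91 ± 0.17 (SD, n = 5) with both, lower in each of 5 same-numbered pairs by 0.827 to 1.16. Against variation between cultures, the exact two-sided permutation p was 0.00794, the smallest that 252 permutations can give, while permutation within 5 pairs cannot go under 0.0625 and so decides nothing. Against a shift shared by genes of like intensity, its median lay below those of 10000 matched random lists (percentile 0), which ran from -0.23 to 0.18. With the Actb covariate 98.5% of it was kept (-0.96), which does not exclude RNA quality that differs between groups, for the reason given above. RNA quality and cell density stay open, and transcripts do not count divisions. A hypothesis for other data is that IL-6 may slow division of cells that receive IL-4.

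Of the 1555 probe sets without a gene name, which no comparison of genes used, 523 passed the filter. Higher than in unstimulated cells were 141 with IL-4, 91 with IL-6, 86 with IL-10, 163 with IL-4 plus IL-6 and 165 with IL-4 plus IL-10. Without names they were not followed further.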

How the results depend on the processing

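The settings that add a random block to the set term, and that keep arrays of 1 set only, were chosen after the results were seen.

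Of 503 values of named genes, 434 kept their direction and their side of the threshold in every one of 18 settings that gave a value, and of 325 list results 171 did. Leaving out single arrays changed the call of 29 genes' values and 35 list results. Counts of called genes stayed within 1.5 times under quantile normalization, median centring, the mean of a gene's probe sets, eBayes with trend and robust, array weights, and only the groups compared.

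Requiring an absolute log2 difference of at least 1 leaves fewer genes by its construction. Against unstimulated the counts were then 293 (IL-4), 120 (IL-6), 149 (IL-10), 637 (IL-4 plus IL-6) and 540 (IL-4 plus IL-10). For IL-4 plus IL-6 they were 383 against IL-4 and 486 against IL-6, and for IL-4 plus IL-10 they were 217 against IL-4 and 469 against IL-10. They were 213 and 121 for the interactions with IL-6 and IL-10, 20 for IL-10 against IL-6 and 59 between the combinations. An adjusted p under 0.01 left 1033 for the interaction with IL-10 and 120 for IL-10 against IL-6. The filter at the 75th percentile tested 4181 genes, and fewer genes tested gave fewer calls. These were 2747, 3301 and 3258 against unstimulated (IL-4, IL-4 plus IL-6, IL-4 plus IL-10), 2799 and 3082 for IL-4 plus IL-6 against IL-4 and IL-6, and 2661 and 2844 for IL-4 plus IL-10 against IL-4 and IL-10.

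IL-10 against IL-6 was the count that moved most. From 850 it became 417 without the filter, 1361 with every probe set by itself and 1788 with the replicate block, which pairs these groups across the sets. With the set term it was 7, and 17 with the set term and the random block. Leaving out single arrays gave 89 to 644, with the lowest value without IL-10 replicate 2. Median centring moved the share of higher calls from 52.7% to 66.3%. The set term also lowered IL-4 plus IL-10 against IL-4 to 2370, and the combinations against each other to 1159 (1840 with the random block). These comparisons lie between the sets, so the term rests on the unstimulated arrays alone. Arrays of the second set alone, which hold fewer controls, gave 1394 genes for IL-10 against unstimulated. An estimated correlation between genes reduced the called lists from 121 to 17. Separate controls raised the correlation of the IL-6 and IL-10 effects from 0.840 to 0.944. The cause was not tested for these changes.

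Some results reversed with the set term, to the same values with and without the random block. In IL-10 against IL-6 these were Arl2bp (-0.29), Gabarapl1 (-0.29), Kri1 (-0.26), Rab5c (-0.21), Ms4a1 (0.057) and Malat1 (0.0070). The lists there were alternative activation (0.027), classical inflammatory activation (-0.075), MHC class II presentation (0.038) and cholesterol biosynthesis (-0.088). Between the combinations these were Prmt1 (-0.49), Kri1 (-0.11), Ms4a1 (0.0060), the scavenger, complement and Fc receptor list (0.12) and the lysosome list, whose median stayed negative (-0.034) while its test turned. In IL-4 plus IL-10 against IL-4 it was Igkv8-30 (0.058). Ctsb in IL-4 plus IL-6 against IL-6 went from 0.032 to -0.19 with the mean of its probe sets and -0.56 with every probe set by itself, and its interaction with IL-6 from 0.059 to -0.23 with every probe set by itself. Probe sets of Ctsb were called in opposite directions there, and the cause was not tested.

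The replicate number as a block leaves unstimulated replicates 6 to 8 alone and puts the IL-10 groups in blocks with same-numbered arrays of the first set, with which they do not vary together. In comparisons within the first set, and of IL-4 plus IL-10 with IL-10, it gained 4 calls of named genes, gained 6 and lost 5 of lists, and changed no other call of these. In the other comparisons it lost 2 calls of genes and gained 4 and lost 4 of lists, which rest on pairs across the sets and are not read further.

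No value exists with arrays of 1 set only for IL-10 against IL-6, IL-4 plus IL-10 against IL-4, the combinations against each other and the interaction with IL-10, whose groups lie in different sets. Lists have no value with every probe set by itself. Signal over background limits what could be tested: without detection calls, the filter at log2 6.99 stands for it, and genes under it, such as Ern1, have no result.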

Other observations

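The tests of B-lineage RNA and of the interferon list between the sets, the conditions that an exact interval and the shares on single numbers lie under 50%, all splits that part every pair, and the setting with arrays of 1 set only were chosen after the results were seen.

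Heat shock genes were higher with IL-4 (8 higher and 0 lower of 12, padj = 0.000471, estimated padj = 0.175) and lower with IL-6 (0 higher and 7 lower of 12, padj = 0.0227, estimated padj = 0.295), and IL-4 raised them on top of IL-6 (9 higher and 0 lower of 12, padj = 0.00156, estimated padj = 0.196) and of IL-10 (7 higher and 0 lower of 12, padj = 0.00183, estimated padj = 0.223). Fatty acid oxidation followed the same directions with IL-4 (12 higher and 1 lower of 20, padj = 0.000208, estimated padj = 0.175) and IL-6 (0 higher and 10 lower of 20, padj = 0.00615, estimated padj = 0.21), the coactivator Ppargc1b rising 4.89-fold with IL-4. Adding IL-6 to IL-4 lowered that list (2 higher and 14 lower of 20, padj = 0.00376, estimated padj = 0.315), and between the combinations it was higher with IL-10 (12 higher and 1 lower of 20, padj = 0.0154, estimated padj = 0.511). Macrophage markers were lower with IL-4 (1 higher and 9 lower of 11, padj = 0.000376, estimated padj = 0.192), Cd14 at -1.78 ± 0.055 and Fcgr1 at -2.26 ± 0.063, and when IL-4 was added to IL-6 (0 higher and 8 lower of 11, padj = 0.000456, estimated padj = 0.196) or IL-10 (1 higher and 8 lower of 11, padj = 0.000892, estimated padj = 0.223). Of that list, 6 genes also stand in other lists. Erythroid and megakaryocyte markers were higher with IL-6 (2 higher and 0 lower of 4, padj = 0.0155, estimated padj = 0.138) and IL-10 (3 higher and 0 lower of 4, padj = 0.0134, estimated padj = 0.151). Hypoxia genes were lower with IL-4 plus IL-10 than with IL-4 plus IL-6 (2 higher and 7 lower of 12, padj = 0.00552, estimated padj = 0.377, and padj = 0.327 with a term for the set). Their negative interaction with IL-10 (0 higher and 3 lower of 12, padj = 0.0108) was lost with an estimated correlation and with the set term (padj = 0.0698). Adjusted over the list alone, counts were 13 higher and 1 lower (IL-4) and 0 higher and 11 lower (IL-6) in the fatty acid oxidation list. Between the combinations they were 2 higher and 8 lower in the hypoxia list, and no other count above changed.

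Not called by limma's camera in any comparison were glycolysis (padj from 0.0572 to 0.995), cystatins and stefins (0.134 to 0.883), and markers of neutrophils (0.116 to 0.969), dendritic cells (0.135 to 0.964) and mast cells with basophils and eosinophils (0.125 to 0.964). Fry, which sets no list against other genes, had padj under 0.05 in 35 of 65 results of these 5 lists. Against unstimulated these held neutrophil markers with IL-4 (0 higher and 6 lower of 9, padj = 0.000918) and IL-4 plus IL-6 (1 higher and 7 lower, padj = 0.00102) and dendritic cell markers with IL-4 plus IL-6 (3 higher and 0 lower of 5, padj = 2.64e-12), so these markers moved with stimulation. Glycolysis passed camera in the interaction with IL-6 without IL-4 replicate 1 (padj = 0.0453), IL-4 plus IL-6 replicate 1 (padj = 0.038) or unstimulated replicate 7 (padj = 0.0414), and in IL-10 against IL-6 without IL-10 replicate 1 (padj = 0.0071). It also passed in that interaction without the filter, with the mean of a gene's probe sets, with trend and robust, and with array weights (padj from 0.0234 to 0.0482). Neutrophil markers passed in IL-4 plus IL-10 against IL-10 without IL-4 plus IL-10 replicate 2 (padj = 0.0466), dendritic cell markers in IL-4 plus IL-10 against unstimulated with arrays of 1 set only (padj = 0.0467), and cystatins and stefins in the interaction with IL-10 with the mean of a gene's probe sets (padj = 0.0277). Among stromal markers only Postn was measured, over the filter only with IL-4 plus IL-6 (1.65 ± 0.10 against unstimulated), so no change is read in other groups. Among lymphocyte and NK cell markers 2 were measured, Cd79b, at -1.17 ± 0.21 with IL-4 plus IL-10, a group of the second set whose mean lies under the filter, and Ms4a1, under the filter in unstimulated and IL-4 plus IL-10 arrays.

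The 850 genes called between IL-10 and IL-6 were weighed as a difference between the sets of arrays. Across genes, which are not independent replicates, unstimulated replicates 6 to 8 minus 1 to 5 correlated with IL-10 minus IL-6 at r = 0.837, so most of this comparison is consistent with a difference between the sets. The 448 genes higher with IL-10 had a median of 0.199 in unstimulated replicates 6 to 8 minus 1 to 5. It was 0.156 to 0.218 without single arrays, against at most 0.0724 for genes of like intensity. Selected across the sets, the 448 would show this under any set difference, so it decides nothing. RNA of B-lineage cells in the first set (Ighm at 12.30 in its unstimulated arrays, against 11.09) stays open. RNA quality, not tested, does too. The interferon list is another matter, since its median in unstimulated replicates 6 to 8 minus 1 to 5 was 0.025, where a difference between the sets would need about its difference between IL-10 and IL-6. Its score was 0.24 ± 0.064 (SD, n = 5) with IL-6 and -0.060 ± 0.057 (SD, n = 3) with IL-10, so a lower interferon response with IL-10 may be biological, a hypothesis that cytokine lots or cultures differing between the sets leave open.

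Whether IL-6 amplifies the response to IL-4 was tested on genes raised at least 2-fold on arrays 1 and 2, with the interaction measured on arrays 3 to 5. Of 136 genes raised by IL-4, 37.5% had a positive interaction with IL-6 (exact 95% interval 29.4% to 46.2% if genes were independent, and 38.2% to 40.4% on the arrays of single numbers), with a median of -0.19, against 48.5% of all genes. Compression of large folds may lower these values, so amplification stays open. The alternative activation list had a median of 0.38 (14 higher and 6 lower of 31, and 0.414, padj = 0.00822, with the replicate block). Of 82 genes raised by IL-6, 50% had a positive interaction (38.7% to 61.3%), a value on the bound set beforehand and inside its own interval, so it decides nothing.

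Other splits of the same arrays into groups of the same sizes were fitted with limma on the groups compared, 100 splits where more exist. In all 13 comparisons no other split gave as many called genes. Among these splits, which ignore the pairing of arrays by number, chance can be excluded against unstimulated for IL-4 (4091 genes, the highest other split 1780), IL-6 (2628, other 336), IL-10 (2076, other 532), IL-4 plus IL-6 (5129, other 2827) and IL-4 plus IL-10 (4915, other 3). It can be excluded for IL-4 plus IL-6 against IL-4 (4413, other 0) and IL-6 (4935, other 0), IL-4 plus IL-10 against IL-4 (3965, other 0), IL-10 against IL-6 (935, other 1) and the combinations (2839, other 0). The interaction splits (IL-6 2877, other 2414, IL-10 1517, other 1091) mix in single-cytokine effects and decide nothing. IL-4 plus IL-10 against IL-10 allows only 10 splits, too few for a share under 0.05 (3880, other 0). Excluding chance does not separate stimulation from set where the groups lie in different sets. Of the 31 other splits that part every same-numbered pair, the highest counts were 1258, 578 and 2563 for IL-4, IL-6 and IL-4 plus IL-6 against unstimulated. With the pairing kept, IL-10 and IL-4 plus IL-10 against unstimulated allow 7 others (highest 15 and 30), IL-4 plus IL-6 against either cytokine allows 15 (highest 0 in each) and IL-4 plus IL-10 against IL-10 allows 3 (highest 0), too few for a share under 0.05.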
